A study of Mus musculus with 34 samples.

How the data were processed

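Nuclei of mouse hippocampus were profiled by droplet single-nucleus RNA sequencing with 3' chemistry, 1 library per sample. The authors made the counts with Cell Ranger 2.0.1 on the mm10 genome, and the deposited values are UMI counts per gene and barcode, 1 raw matrix of every barcode and 27998 genes per library. These counts were checked to be whole numbers with no scaling. A filtered matrix deposited for the whole series names no sample. All 4969 of its barcodes were among the 6714 that passed the filters here for E4_5mo replicate 4, before doublets were removed, with equal counts in every gene. At most 56 were among those of any other library. It holds no other data and was not used. The names of a pair of 15-month libraries' files say 14 months, and the labels were used.

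Nuclei were called anew in every raw matrix. The minimum number of UMIs was the 99th percentile of the top 3000 barcodes divided by 25, where Cell Ranger divides by 10, because nuclei of glia hold few UMIs. This divisor was chosen after the barcode totals were seen and before any comparison between groups. The minimum came to 273 to 538 UMIs over the 32 libraries (683 to 1344 with a divisor of 10). Nuclei also needed at least 300 UMIs, at least 200 genes and at most 5% mitochondrial UMIs, which removed 849 barcodes. The expected doublets, 0.8% per 1000 nuclei, were removed by Scrublet score, 9287 in the 32 libraries. This left 4198 to 7130 nuclei per library (median 5595). Before doublets were removed, nuclei held 56.8 to 80.4% of the UMIs of their library. Median UMIs per nucleus by library and Xist and Y gene values are from that stage too. Droplets of at most 50 UMIs served as the profile of free RNA.

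All 191455 nuclei, with the Syn-Cre libraries, were clustered together on 2000 variable genes, without Apoe, class I, mitochondrial and sex chromosome genes. The steps were log normalisation, 30 principal components, a graph of 15 shared nearest neighbours and Leiden clustering at resolution 1.0, which gave 37 clusters. A cluster took the class whose fixed markers were detected in at least 10% of its nuclei and 2-fold above all others, with at least 3 markers. A cluster with markers of a pair of classes, or shallow with no marker among its top 10 genes, stayed unnamed. Between 12.8 and 18.1% of nuclei, by group, had no name and were left out. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5 and leidenalg 0.10.2. Positions came from the GENCODE mouse annotation, in which 99.0% of the features were found.

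Samples were grouped by their labels into 8 groups of 4, by human allele and age, and the mouse was the unit of replication. UMI counts were summed per library and class, and a library with under 20 nuclei of a class was left out of that class. Each of 8 main classes was fitted over all groups with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood F-test, two-sided), with the code letter of the sample title (H, A, B or C) as a covariate. The letter holds as many E3 as E4 libraries. Contrasts were E4 against E3 as the mean of the 4 ages, the same at each age, 20 against 5 months as the mean of both genotypes, and the difference in age change between genotypes. A gene was called at a Benjamini-Hochberg adjusted p of 0.05 within its class. CPM of gene comparisons are on the TMM scale over the UMIs of tested genes. Those of H2-D1 and H2-K1 in each group of age and genotype, of Apoe, of the Syn-Cre libraries, of X and Y genes and of genes with a floor are over all UMIs of the nuclei named, without TMM. CPM are given as mean ± SD, with SE from the fit. For 31 gene lists, fry (limma 3.58.1) tested whether members moved 1 way on balance, adjusted over lists and classes, and camera was run with a preset correlation of 0.01 and with an estimated one. Fry does not compare a list with other genes.

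Shares of nuclei are percents of named nuclei and were compared by two-sided permutation tests with 100000 permutations, as were the Apoe shares. Nuclei with under 1000 UMIs have no thinned share. Age was also compared on the means of library pairs by an exact test. Because shares rise with depth, each nucleus was thinned to 1000 UMIs before the Apoe share was taken. For the split by Apoe, each neuron with an Apoe UMI was matched within its library to the neuron of its class with none and the nearest total of other UMIs. The paired sums were then fitted in edgeR with the library as a block. The same split was made for Clu and Cst3 and for 20 random genes of like detection. Neuronal Apoe and the mean of 7 class I genes were correlated across libraries (Pearson and Spearman, permutation p). Counts over the 2 Syn-Cre libraries have exact Poisson intervals at 95% and no test. A gene with 0 UMIs in a group was set to a floor of 3 counts over the group for a fold. Intervals and floors cover counting error only.

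The contrasts, tests, lists, markers and the alternatives listed first were set before the data were examined, and so was the rule for naming genes. By that rule the text always gives Apoe, H2-K1, H2-D1 and B2m. For each class it draws on the 5 largest rises and 5 largest falls among called genes of at least 10 CPM with 1 direction in at least 3 of 4 ages (genotype) or in both genotypes (age). It adds up to 4 called members of each list and the 5 largest rises and falls of the Apoe splits. The age changes of Serpina3n within each genotype and the values of Clu and Cst3 lie outside the rule and the first were chosen after they were seen, while the others are fixed controls. The human alleles have no feature of their own in the deposited gene list, so how many of their reads fall on the mouse Apoe feature is unknown.

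Alternatives were DESeq2 1.42.0 in place of edgeR, no TMM factors, no filter on low counts, no code letter, a block for library pairs, at least 1000 UMIs per nucleus, doublets removed at 2 times the rate and at most 1% mitochondrial UMIs. For the Apoe measures they were no matching on depth, no thinning and thinning to 500 UMIs, and for shares a denominator of neurons or of glia. Each library was also left out in turn. The Cell Ranger minimum, the removal of the 4 letter H libraries, and for age the sums of library pairs (16 pairs, fitted on age and code letter) were added later, as were splits of whole pairs. A pair is an E3 and an E4 library of 1 age with adjacent title numbers. To check that they pair samples, group means were removed and expression correlated, and 16 of 16 pairs were above 0.1 (lowest 0.233, median 0.668), against a median of -0.281 over 48 other pairs of the same age.

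The fits were tested on simulated data with the spread of the real libraries and 200 changed genes. In DG granule nuclei 81.2% of genes with a log2 change of 0.5 and 97.9% of those with 1 were called between genotypes, and 61.9% and 88.5% between ages. Between genotypes these shares were 67.0% and 100% in oligodendrocytes, 62.0% and 100% in astrocytes and 51.7% and 98.8% in microglia. For age they were 38.0% and 90.6% in oligodendrocytes and 22.5% and 80.2% in microglia. False calls were 2.27 to 7.58% of all calls. The simulated libraries were drawn independently, without the variation that library pairs share. These rates therefore do not cover that variation, which bears most on age, since both libraries of a pair have 1 age.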

Results

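The series holds single-nucleus RNA sequencing of mouse hippocampus, by droplet capture of nuclei sorted on the DNA stain DAPI. The mice carried human APOE3 or human APOE4 in place of the mouse gene (targeted replacement, here E3 and E4), and 32 libraries form 8 groups of 4, for both alleles at 5, 10, 15 and 20 months. A further 2 libraries, 1 per allele, came from 15-month mice with a floxed human allele and Syn-Cre, a transgene that expresses Cre recombinase in neurons. The 32 libraries held 13367805 to 37415229 unique molecular identifiers (UMIs, median 21478746), and 181778 nuclei were kept from them. The median was 1466 to 3383 UMIs per nucleus and library, before doublets were removed. The Syn-Cre libraries were shallower, with 9598091 and 13747397 UMIs and medians of 810 and 1209 UMIs per nucleus. Median UMIs per nucleus averaged 1745 at 20 months and 2318 at 5 months (n = 8 each, permutation p = 0.0049). That test permuted single libraries and does not allow for the variation that the library pairs of an age share. Total UMIs did not differ detectably by genotype (permutation p = 0.80). Every value for Apoe is of the mouse gene's feature (ENSMUSG00000002985, mm10 chromosome 7, 19696109 to 19699188), because the deposited gene list holds no human gene.

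The first comparison asks what differs between E4 and E3 libraries in each hippocampal cell type. The share of tested genes called was high in some segments of the genome, as described below. Whether a difference comes from the allele or from other differences between the lines was not tested. In granule neurons of the dentate gyrus (DG), Nrg1, which encodes neuregulin 1, a ligand of ErbB receptors, fell from 1194 ± 300 normalised CPM (SD, n = 16) in E3 to 417 ± 104 in E4 (log2 -1.51, SE 0.058, edgeR adjusted p = 5.76e-20). Serpina3n, a secreted protease inhibitor and a marker of reactive astrocytes, rose in the same nuclei from 2.06 ± 0.749 to 16.2 ± 5.78 CPM (log2 3.03). Gabra2, the alpha-2 subunit of the GABA-A receptor, fell in all 4 neuronal classes, from 708 ± 101 to 522 ± 68.3 CPM in DG granule neurons (log2 -0.44), with log2 changes of -0.37, -0.35 and -0.32 in CA1 pyramidal, CA2/CA3 pyramidal and interneuron nuclei. Each of these changes kept its direction at 4 of 4 ages.

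The largest changes were switches of single transcripts that recurred from class to class. Gm15594, an antisense transcript inside the Cttnbp2 gene on chromosome 6 (18424684 to 18427885), rose from 37.7 ± 8.47 to 675 ± 107 CPM in DG granule neurons and by 4.23, 4.15 and 4.06 on the log2 scale in CA1, CA2/CA3 and interneuron nuclei. Tex21, a testis-expressed gene, was nearly absent in E4, at 0.23 ± 0.364 CPM in CA1 against 21.4 ± 5.78 in E3, and Mov10l1, an RNA helicase known from the germ line, fell in the 3 excitatory classes (log2 -3.61 to -3.87) and in interneurons (log2 -3.21). Gm10600 had 0 UMIs in all 16 E4 libraries of CA1 nuclei and 23.2 CPM over the E3 libraries, at least 337-fold lower with 3 counts over the group as the floor. Leprotl1 rose by 1.74, 1.68, 2.03 and 1.85 in the 4 neuronal classes, Gm20404 by 2.14, 2.05, 2.11 and 1.85, and D8Ertd82e by 1.60 in DG and 1.52 in CA1. Rdh13, a retinol dehydrogenase, fell in CA1, CA2/CA3 and interneurons (log2 -1.39, -1.34 and -0.80), Ppp6r1, a regulatory subunit of protein phosphatase 6, fell in DG (log2 -1.14), and so did the histone variant gene H2afz in CA2/CA3 (log2 -1.21). Smim18 rose by 1.47 in CA2/CA3 and the pseudoautosomal gene Erdr1 by 1.26 to 1.31 in CA1, CA2/CA3 and interneurons.

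In interneurons, Asns, asparagine synthetase, rose from 8.21 ± 3.81 to 15.4 ± 4.83 CPM (log2 0.93, adjusted p = 7.31e-05), and Aldh1l2, a mitochondrial folate enzyme, from 7.21 ± 3.07 to 19.5 ± 5.67 CPM (log2 1.38). Mx1, an interferon-induced GTPase, had 147 UMIs over the 16 E4 libraries and 0 over the 16 E3 libraries, at least 56.6-fold higher with the same group floor. Npas4, an activity-induced transcription factor, fell by 1.04 (adjusted p = 0.040), a call that ended in 11 of the 16 leave-outs in which it was tested (highest adjusted p = 0.0875).

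**Figure D1:**
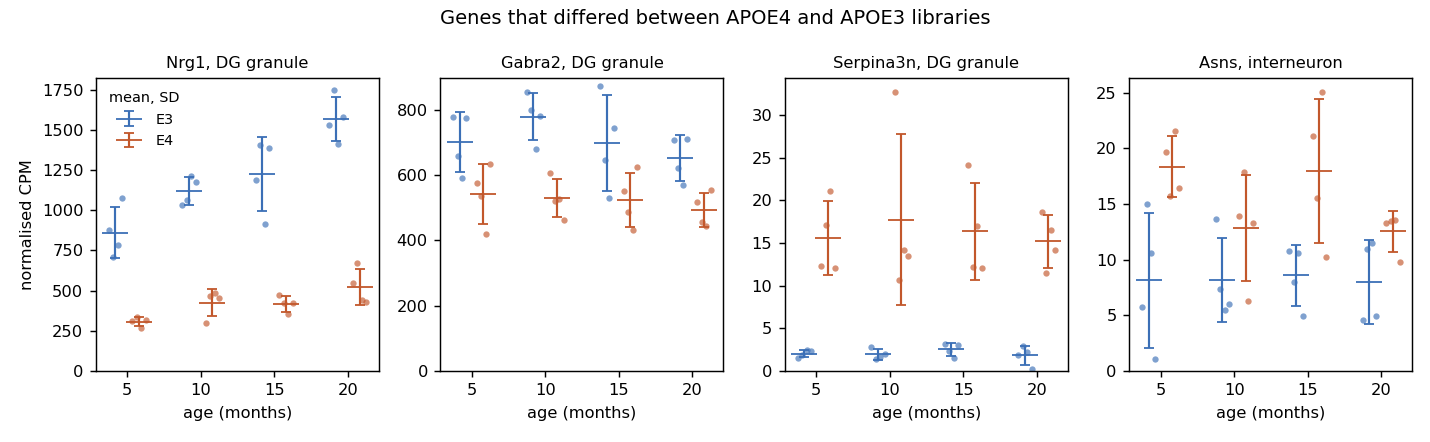
Normalised CPM of Nrg1, Gabra2 and Serpina3n in DG granule nuclei and of Asns in interneuron nuclei, by age in months and genotype. Each point is 1 library and the bars give the mean and SD of the 4 libraries of a group. Nrg1 averaged 417 CPM in E4 and 1194 in E3 over all ages.

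In oligodendrocytes, Ninj2, an adhesion molecule of glia, fell from 619 ± 74.9 to 276 ± 24.7 CPM (log2 -1.17, SE 0.051), and Cttnbp2, a cortactin-binding protein, from 640 ± 42.8 to 318 ± 31.4 (log2 -1.01). Aim2, a sensor of cytosolic DNA, rose from 16.6 ± 8.98 to 49.8 ± 12.1 CPM (log2 1.63), Serpina3n from 7.75 ± 9.20 to 16.7 ± 6.64 (log2 1.69) and Gm16193 by 3.90. Tex21 (log2 -5.71), Ppp6r1 (log2 -1.44) and the DNA glycosylase gene Mbd4 (log2 -1.21) fell. In oligodendrocyte precursors (OPC), Nrg1 rose from 920 ± 133 to 1435 ± 235 CPM (log2 0.63, adjusted p = 9.80e-11), opposite in direction to DG granule neurons. Zdhhc2, a palmitoyltransferase, rose in OPC by 0.70 and Pdgfrl, a receptor-like protein, by 1.35, and Tia1, an RNA-binding protein of stress granules, fell in OPC (log2 -0.85) and astrocytes (log2 -0.98). Astrocytes also had less Slc25a18, a mitochondrial glutamate carrier (220 ± 64.6 to 121 ± 45.3 CPM), and more Slc7a2, a transporter of cationic amino acids (log2 0.80, adjusted p = 0.0058, and 0.18 without E4_20mo replicate 3). In microglia, Rapgef5 rose by 0.58 and Arhgap24 fell by 0.73 (adjusted p = 0.028, and up to 0.13 in the 9 of 32 leave-outs that end the call).

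In counts, 137 genes were higher and 136 lower in E4 DG granule nuclei (of 12736 tested), 125 and 179 in CA1, 59 and 90 in CA2/CA3, 121 and 150 in interneurons, 48 and 60 in oligodendrocytes, 5 and 4 in OPC, 3 and 4 in astrocytes, and 1 and 1 in microglia. Of the 751 genes called in any class, 188 were called in 2 or more, 180 of them in 1 direction. DG and CA1 shared 106 genes with the same direction and 0 with opposite directions, from sums over the same 32 libraries. With the library pair as a block in place of the code letter, the counts were 429 in DG, 479 in CA1 and 225 in CA2/CA3. With no code letter they were 124, 142 and 88, with 128 in interneurons and 55 in oligodendrocytes.

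**Figure D2:**
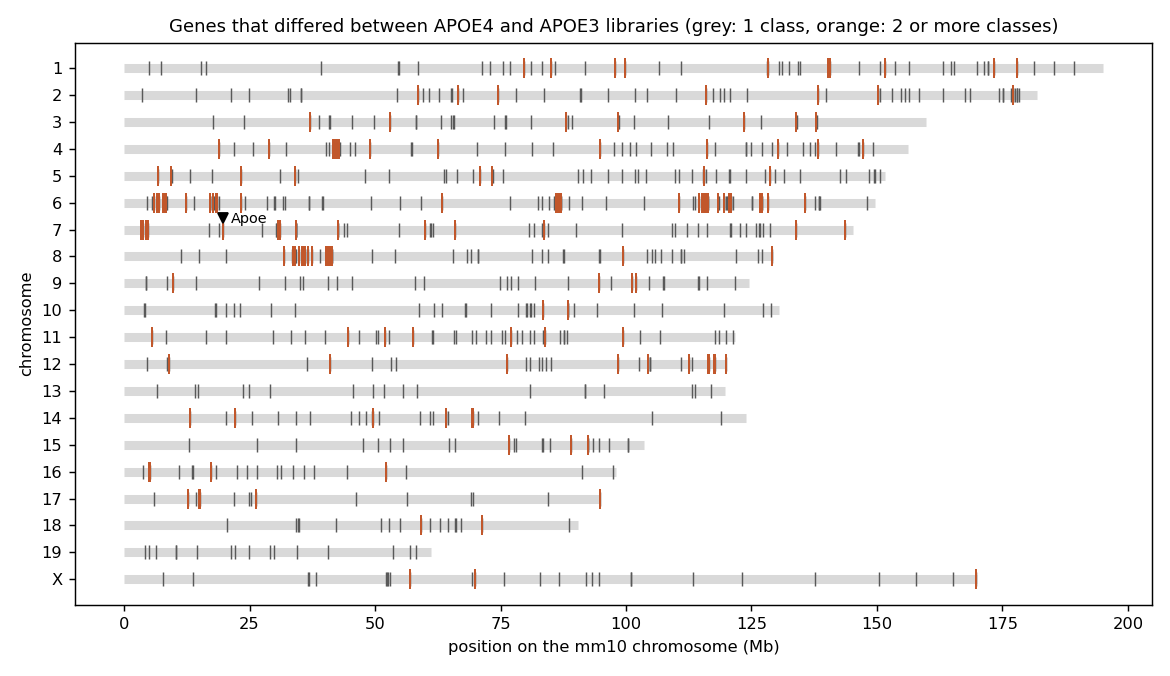
Genes called between E4 and E3 along the chromosomes, drawn to scale in Mb. Grey marks are genes called in 1 class, orange marks genes called in 2 or more, and the position of Apoe on chromosome 7 is marked. Chromosome 6 has the largest share, 13.6% of 697 tested genes.

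Calls were uneven along the genome. Between bases 30000001 and 40000000 of chromosome 8, 16 of 28 tested genes were called in some class (57.1%), among them Nrg1, Leprotl1, Smim18 and D8Ertd82e, and Zdhhc2, Pdgfrl, Slc7a2, Asah1 and Gm16193 follow within 2 Mb of it. In the first 10 Mb of chromosome 6, where Asns lies, 11 of 26 were called (42.3%), and in the next 10 Mb, with Cttnbp2 and Gm15594, 10 of 22 (45.5%). Between bases 40000001 and 50000000 of chromosome 8, 13 of 42 were called (31.0%). In the first 10 Mb of chromosome 7 it was 16 of 66 (24.2%), and between its bases 30000001 and 40000000 it was 12 of 78 (15.4%). Between bases 110000001 and 120000000 of chromosome 6, 19 of 79 were called (24.1%).

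Of 31 gene lists fixed before the data were examined, 2 of 201 list tests passed the threshold for E4 against E3. These were reactive astrocyte genes in DG granule (8 measured, mean log2 0.20, median -0.13, adjusted p = 0.040) and CA2/CA3 nuclei (7 measured, mean 0.31, median 0.03, adjusted p = 0.040). In both, Serpina3n was the only member called, adjusted over the list alone also 1, and neither held with an estimated correlation (adjusted p = 0.94). Glutamate receptor genes gave 7 calls over 8 classes, all lower (adjusted over the list alone, 2 higher and 9 lower). Grm7, a presynaptic metabotropic receptor, fell by 0.23 in DG, and Grin2b, an NMDA receptor subunit, in CA1 (log2 -0.12), the second with a highest adjusted p = 0.074 over single libraries left out. Glycolysis gave 5 calls, all lower (adjusted over the list alone, 1 higher and 6 lower), of which Gpi1, glucose-6-phosphate isomerase, made 4, at -0.21, -0.25, -0.37 and -0.27 in DG, CA1, CA2/CA3 and interneurons. The DG call of Gpi1 ended without any of 15 libraries (highest adjusted p = 0.078). GABA signalling gave 4 calls, which were Gabra2 in each neuronal class (adjusted over the list alone, 7 higher and 8 lower). Lysosome and autophagy gave 2 higher, Atg7 in DG (0.18) and CA1 (0.26), and 1 lower, Asah1 in interneurons (-0.26). The 30 lists other than the reactive astrocyte list had no test past the threshold, the smallest adjusted p = 0.26 being that of vascular RNA in CA1. The call of Atg7 in DG ended without any of 20 libraries (highest adjusted p = 0.093) and that of Asah1 without E3_10mo replicate 1 (0.056).

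At single ages, summed over the 8 classes, 183 genes differed at 5 months, 264 at 10, 174 at 15 and 157 at 20 months. With the library pair as a block, 598 differed at 10 months. Without the 4 libraries of code letter H, 106 differed at 15 months.

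The series title names MHC class I, so the class I heavy chain genes with B2m, their light chain, were tested as a list. Between E4 and E3 the mean log2 change was 0.02 in DG granule, 0.04 in CA1, 0.03 in CA2/CA3 and -0.06 in interneuron nuclei, 0.19 in oligodendrocytes, -0.07 in OPC and -0.01 in microglia, with a smallest adjusted p of 0.74. No member was called in any of the 7 classes by edgeR, over all genes or adjusted over the list alone. H2-D1, for example, was at 9.80 ± 3.02 CPM in E4 and 8.01 ± 2.38 in E3 DG granule nuclei (log2 0.30, SE 0.13, adjusted p = 0.31, E4 higher at 4 of 4 ages), H2-K1 at 1.81 ± 1.05 and 1.51 ± 0.793 CPM, and B2m at 5.39 ± 1.75 and 6.64 ± 1.60 CPM. In astrocytes no member passed the filter on low counts.

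The second comparison asks what changes from 5 to 20 months in both genotypes together. Each age was taken from 4 library pairs, which share variation, so counts with the pairs summed are given too. The clearest change was in oligodendrocytes. C4b, a complement component, rose from 21.0 ± 3.78 to 250 ± 113 CPM (n = 8 each, log2 3.44, adjusted p = 3.97e-14). H2-D1, a class I heavy chain, rose from 13.5 ± 3.59 to 46.2 ± 19.6 CPM (log2 1.83, adjusted p = 2.48e-07) and H2-K1 from 6.76 ± 5.49 to 14.7 ± 5.78 CPM (log2 1.29, adjusted p = 0.015). Clic5, a chloride channel family member, rose by 2.02, Serpina3n by 1.97, Rnf125, a ubiquitin ligase, by 1.86, the transcription factor Stat3 by 0.72 and the cytokine gene Csf1 by 0.57. Nckap5 fell by 1.95 on the log2 scale (126 ± 32.3 to 33.4 ± 9.05 CPM), and Gm5087 (log2 -1.61), the guidance gene Sema3d (log2 -1.59), Sytl5 (log2 -1.31) and the synaptic vesicle gene Synpr (log2 -1.25) fell with it. In total 109 genes rose and 44 fell, and 73 were called with no code letter, 101 without E4_5mo replicate 1 and 96 with library pairs summed.

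**Figure D3:**
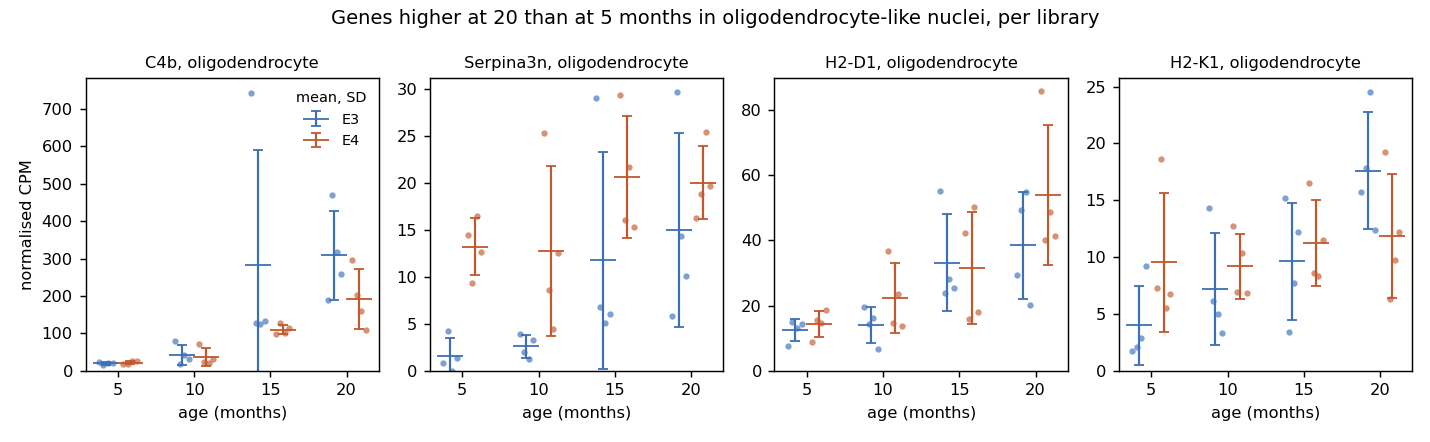
Normalised CPM of C4b, Serpina3n, H2-D1 and H2-K1 in oligodendrocyte nuclei by age in months and genotype. Each point is 1 library and the bars give the mean and SD of the 4 libraries of a group. C4b averaged 21.0 CPM at 5 months and 250 at 20 months.

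Over all UMIs of oligodendrocytes, H2-D1 had E3 means of 12.1 ± 3.20, 13.5 ± 5.14, 32.4 ± 13.7 and 38.6 ± 16.6 CPM and E4 means of 14.1 ± 4.05, 21.7 ± 9.88, 31.5 ± 17.4 and 53.5 ± 21.8 CPM at 5, 10, 15 and 20 months (n = 4 each). H2-K1 rose mostly in E3, from 3.8 ± 3.3 CPM at 5 months to 17.6 ± 5.2 at 20 months. In E4 it stood at 9.4 ± 6.2 and 11.8 ± 5.5 CPM, and the difference in age change between genotypes was not called. As a list, class I rose in oligodendrocytes (5 measured, 2 higher, 3 adjusted over the list alone, mean log2 0.74, adjusted p = 0.045), and B2m stood at 12.4 ± 6.19 and 19.5 ± 8.68 CPM (adjusted p = 0.10). The list's call was lost with an estimated correlation (adjusted p = 0.16), with library pairs summed (0.21) and in 19 of 32 runs without 1 library (lowest mean log2 0.66). It was also lost with no code letter (adjusted p = 0.40), with doublets removed at 2 times the rate, at a mitochondrial maximum of 1% and without the letter H libraries, with mean log2 changes of 0.67 to 0.74. The call of H2-K1 ended without E3_5mo replicate 1 (adjusted p = 0.11), E4_20mo replicate 1 (0.066), E3_20mo replicate 3 (0.091) or E4_5mo replicate 4 (0.056), with no code letter (0.084) and with library pairs summed (0.066). In microglia, where class I levels were highest, H2-D1 was at 424 ± 191 CPM at 5 and 603 ± 191 at 20 months (adjusted p = 0.55) and H2-K1 at 256 ± 128 and 477 ± 204 (adjusted p = 0.55). In DG granule nuclei H2-D1 was at 8.34 ± 2.11 and 9.11 ± 3.47 CPM (adjusted p = 0.68).

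Astrocytes at 20 months had more C4b (97.0 ± 21.1 to 265 ± 132 CPM, log2 1.44) and more Gfap, the intermediate filament of reactive astrocytes (164 ± 43.6 to 328 ± 100 CPM). Both calls ended with no code letter (adjusted p = 0.059 and 0.12) and at a minimum of 1000 UMIs per nucleus (0.77 and 0.56), and that of Gfap also with no filter on low counts (0.067) and with the Cell Ranger minimum (0.10). 1700112E06Rik rose by 0.81 (adjusted p = 0.0067, and 0.052 without E3_20mo replicate 4), and 0 of 2609 genes fell by edgeR or DESeq2 (197 were at an unadjusted p under 0.05 in either direction). Without E3_20mo replicate 4 the astrocyte count was 2, without E4_5mo replicate 4 it was 3, with library pairs summed it was 3 and without E3_15mo replicate 1 it was 10. In OPC, Mbp, myelin basic protein, dropped from 276 ± 90.8 to 105 ± 53.6 CPM (log2 -1.28), Enpp6, a marker of newly formed oligodendrocytes, from 85.6 ± 39.2 to 22.3 ± 26.8 CPM (log2 -1.72). St18 (log2 -1.08), the kinase gene Fyn (log2 -0.86) and the chromatin remodeller gene Chd3 (log2 -1.51) fell as well. Tshz3, a zinc finger transcription factor, rose in OPC by 0.86. In OPC 6 genes rose and 12 fell, 18 in all, against 6 without E4_5mo replicate 1, and 11 without E4_20mo replicate 2, without E4_20mo replicate 3 or with DESeq2, and 17 with library pairs summed. The calls of Enpp6 and St18 ended without any of 12 and 4 libraries (highest adjusted p = 0.40 and 0.35). With DESeq2 Mbp was at adjusted p = 0.079, and with no code letter Enpp6 was at 0.063. Microglia had 0 calls with edgeR or DESeq2 among 1877 genes, with 147 at an unadjusted p under 0.05.

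DG granule neurons changed most among neurons, with 82 genes higher and 47 lower. Camk2d, the delta subunit of calcium/calmodulin-dependent kinase II, rose from 25.2 ± 5.08 to 93.7 ± 8.42 CPM (log2 1.92, adjusted p = 3.94e-10) and Tmem132d from 37.4 ± 7.26 to 95.9 ± 10.7 (log2 1.27). Ptprm, a receptor phosphatase, rose by 1.24, Dchs2, a protocadherin, by 1.22 and the transcription factor Zfhx3 by 0.74. C4b rose from 0.36 ± 0.295 CPM, near the floor of these libraries, to 3.54 ± 1.42 CPM. Both values are far below those in oligodendrocytes and astrocytes, where C4b rose too. Whether free RNA of glia gave the rise in DG granule nuclei was not tested. Robo1, an axon guidance receptor, fell from 101 ± 12.1 to 58.9 ± 12.4 CPM (log2 -0.84), and the fibrillin gene Fbn2 (log2 -0.88) and the glycine receptor gene Glra2 (log2 -0.67) fell too. Without E4_20mo replicate 3 the DG count was 68, without E3_5mo replicate 1 it was 84, and with no code letter it was 43. With library pairs summed it was 55, and 53 of these were among the 129.

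Other neurons changed in few genes with age. CA1 had 9 higher and 2 lower, with 9530026P05Rik up by 0.99, Lin28b, an RNA-binding protein, by 0.94, and Vmn2r85 down (log2 -0.72, adjusted p = 0.041, and up to 0.23 in 12 leave-outs). With library pairs summed the CA1 count was 3, with Lin28b at adjusted p = 0.062 and Vmn2r85 at 0.45. The CA1 count was 4 without E3_5mo replicate 1 or without E4_20mo replicate 3, 6 without E4_5mo replicate 1, 7 without E3_20mo replicate 2 or without E4_5mo replicate 4, and 19 without E3_10mo replicate 3. Tshz3 was the only gene called in CA2/CA3 (12.2 ± 4.72 to 24.7 ± 6.17 CPM, log2 0.92, adjusted p = 0.023) and rose in interneurons by 0.90. The CA2/CA3 call ended without any of 11 libraries (highest adjusted p = 0.39) and with library pairs summed (0.44). Neat1, a nuclear long non-coding RNA, was the other interneuron call (log2 1.17, adjusted p = 0.019, and up to 0.42 in 7 leave-outs), and its adjusted p was 0.41 with DESeq2 and 0.52 with library pairs summed.

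For age, 9 of 201 list tests passed the threshold, and 5 tests passed with an estimated correlation. Reactive astrocyte genes rose in astrocytes (3 measured, 2 called, 3 adjusted over the list alone, mean log2 1.08, adjusted p = 8.35e-05) and in oligodendrocytes (5 measured, 4 called, 4 adjusted over the list alone, mean log2 1.36, adjusted p = 1.38e-06), and both held with an estimated correlation (adjusted p = 8.89e-05 and 2.37e-05). With no filter on low counts, which brings 21 members in, the astrocyte mean was 0.03 (adjusted p = 0.055). Complement rose in oligodendrocytes (3 measured, mean 1.15, median 0.08) with C4b its only call, also adjusted over the list alone, and held with an estimated correlation (adjusted p = 0.00034). In DG granule nuclei complement passed (7 measured, all 7 higher, 1 called, also adjusted over the list alone, adjusted p = 0.016), though not with an estimated correlation (adjusted p = 0.081). The 1 call was C4b, which was near the floor there at 5 months. Cholesterol synthesis rose in interneurons, with 16 of 18 members higher, 0 called over all genes by edgeR and 3 adjusted over the list alone (mean log2 0.28, adjusted p = 0.0099, and 0.017 with an estimated correlation). Neurogenesis genes fell in DG granule (7 measured, mean -0.25, 0 called over all genes or over the list alone, adjusted p = 0.021) and CA1 nuclei (7 measured, mean -0.30, 0 and 3 called, adjusted p = 0.026), with adjusted p = 0.13 and 0.061 with an estimated correlation. Neuron RNA in astrocytes fell (12 measured, mean -0.30, 0 called, 1 adjusted over the list alone, adjusted p = 0.044, and 0.071 with an estimated correlation). Oligodendrocyte RNA in OPC (mean -0.97) was at adjusted p = 0.073, and 0.043 with an estimated correlation. The other 25 lists, counting this one, had no test past the threshold. Leaving out 1 library in turn ended the list calls of complement and neurogenesis in DG granule nuclei in 12 and 4 runs, of neurogenesis in CA1 in 5 and of neuron RNA in astrocytes in 6. With library pairs summed the 2 reactive astrocyte calls and complement in oligodendrocytes held (adjusted p = 0.025, 2.58e-05 and 0.00038). The calls of complement in DG, neurogenesis in DG and CA1, cholesterol synthesis in interneurons and neuron RNA in astrocytes did not (adjusted p = 0.12 each).

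Whether age acts differently in E4 and E3 was tested as an interaction. No gene was called by edgeR or DESeq2 in any class, while 306, 287, 300 and 311 genes stood at an unadjusted p under 0.05 in DG, CA1, CA2/CA3 and interneuron nuclei and 130, 290, 132 and 57 in astrocytes, oligodendrocytes, OPC and microglia. Serpina3n in oligodendrocytes rose with age by 3.34 in E3 and 0.60 in E4 (interaction log2 -2.73, adjusted p = 1). With the library pair as a block 1 gene was called.

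The title also speaks of selective neurodegeneration, which the shares of nuclei address only as relative abundance. Cajal-Retzius neurons fell from 0.673 ± 0.0880% of named nuclei at 5 months to 0.342 ± 0.124% at 20 months (n = 8 each, adjusted permutation p = 0.0052, and 0.0507 with the Cell Ranger minimum). On means of library pairs (n = 4 each) the unadjusted exact p was 0.0286, the smallest possible. No other class reached this value, so it would not pass the threshold after adjustment over the 11 classes. Astrocytes were at 2.97 ± 1.34% and 1.53 ± 0.772% (adjusted permutation p = 0.085), oligodendrocytes at 20.8 ± 3.20% and 25.0 ± 4.26% (0.14), DG granule neurons at 31.0 ± 2.90% and 28.1 ± 5.96% (0.31) and CA1 neurons at 16.2 ± 1.70% and 14.4 ± 2.10% (0.25). As a share of glia, astrocytes differed by -5.60 points at 20 months (adjusted permutation p = 0.023), though on means of library pairs the exact p was 0.086, and 0.086 too for their share of named nuclei. Within letter A they made up 1.58% of named nuclei at 20 and 1.44% at 5 months. Between genotypes, oligodendrocytes were at 23.9 ± 4.52% in E4 and 21.2 ± 3.70% in E3 and DG granule neurons at 29.1 ± 5.94% and 30.8 ± 4.37% (n = 16 each), and the smallest adjusted permutation p over the 11 classes was 0.41. This test permuted genotype within age and did not use the library pairs. Oligodendrocyte means were higher in E4 than E3 in letters A (27.2 and 23.3%), B (20.1 and 18.2%) and C (23.8 and 20.3%). They were lower in H (21.6 and 23.1%).

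The mouse Apoe feature in neurons did not differ detectably between genotypes. After thinning each nucleus to 1000 UMIs, 2.84 ± 1.21% of E4 and 2.83 ± 1.12% of E3 neurons had an Apoe UMI (n = 16 each, permutation p = 0.97, median depth before thinning 2825 and 2910 UMIs). In oligodendrocytes, taken as a class with little Apoe of its own, the share was 2.58 ± 2.78% and 3.44 ± 3.12%, which rests on the deeper nuclei of at least 1000 UMIs (median depth 659 and 706 UMIs, 0 to 10.6% by library), and in astrocytes, its main source in brain, 9.99 ± 7.68% and 10.4 ± 5.38%. Neurons held 18.5 to 67.9 CPM of the Apoe feature, astrocytes 20.3 to 247 CPM and near-empty droplets 75.5 to 208 CPM. The astrocyte median (87.45 CPM) was below that of near-empty droplets (115.9 CPM), while astrocytes of the Syn-Cre libraries held 1388 and 761 CPM. In the 32 libraries the feature may thus capture few reads of the human alleles. Neither the equal levels nor the splits and correlations below can then decide on human APOE in neurons. The 4 libraries of letter H stood apart, with 45.4 to 67.9 CPM in neurons against 18.5 to 39.4 in letters A, B and C.

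**Figure D4:**
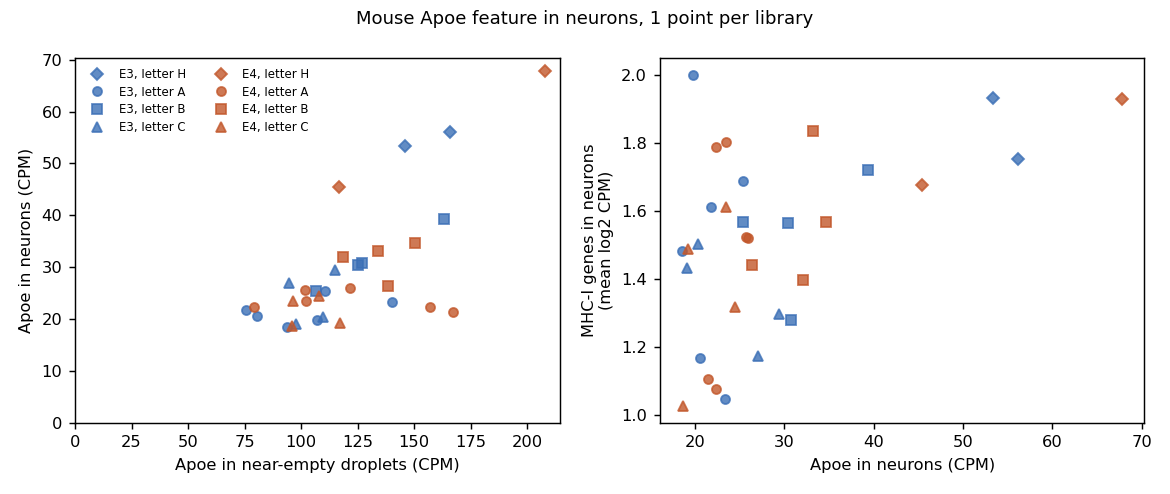
Left, CPM of the mouse Apoe feature in near-empty droplets and in the main neuronal classes, and right, neuronal Apoe against the mean log2 CPM of 7 class I genes, 1 point per library. The 4 letter H libraries lie at 45.4 to 67.9 CPM in neurons, above the others.

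Within libraries, neurons with an Apoe UMI were compared with neurons without one, matched on depth. In DG granule nuclei Malat1 alone was higher (log2 0.09). In CA1, 10 genes were higher and 3 lower, among them Dpm2 (0.41), Nap1l5 (0.41), Tspyl2 (0.34), Mat2a, which makes S-adenosylmethionine (0.25), and Cadps, a factor of vesicle release (-0.14). In CA2/CA3, 8 were higher and 15 lower, with Ivd at 0.42, Srsf10, a splicing factor, at 0.40, Kcnq3, a potassium channel subunit, at -0.22 and Luzp2 at -0.24. In interneurons 3 were higher, Nap1l5 (0.46), Rsrp1 (0.28) and Pnisr (0.27), and 3 lower, Camk4, a calcium-dependent kinase (-0.49), Pdzrn3 (-0.48) and Hs6st3 (-0.46). No class I gene was called, and H2-D1 in DG granule nuclei had 98 UMIs with and 69 without (log2 0.49, unadjusted p = 0.038, adjusted p = 1).

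The same split by other genes shows how much of this any gene gives. Split by Clu, 6, 62, 86 and 182 genes were called in DG, CA1, CA2/CA3 and interneuron nuclei, and by Cst3 0, 5, 1 and 114, the 0 with edgeR and 347 at an unadjusted p under 0.05. Among 20 random genes of like detection, 14, 9, 7 and 4 gave as many calls as Apoe, with maxima of 174, 904, 825 and 143. Without matching on depth, Apoe gave 123, 115, 39 and 88. Counts moved with single libraries, from 1 to 5 in DG, 6 to 20 in CA1, 5 to 37 in CA2/CA3 and 1 to 8 in interneurons, the lowest being without E4_10mo replicate 1, E3_10mo replicate 1, E3_5mo replicate 2 and E3_5mo replicate 1.

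Across mice, neuronal Apoe and the mean of 7 class I genes were correlated in 4 ways, with no pooled value because letter H forms a separate cluster. Over the 28 libraries of letters A, B and C, Pearson's r was 0.19 (permutation p = 0.32, adjusted 0.57) and Spearman's rho 0.22 (p = 0.26). With the mean of each letter removed, r was 0.10 over 32 libraries (permutation p = 0.55, rho 0.17, p = 0.34, adjusted 0.57). Within E4, r was 0.43 (n = 16, permutation p = 0.085, adjusted 0.34, rho 0.36, p = 0.16) and within E3 -0.14 (permutation p = 0.57, adjusted 0.57, rho -0.11, p = 0.69). Without the 2 libraries farthest from the median of Apoe, r was 0.093, 0.089, 0.40 and -0.29 in that order.

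The Syn-Cre libraries, with Cre in neurons, are 1 per allele and have no replicates. Neurons held 22.7 CPM of the Apoe feature in the E3 library (94 UMIs, 95% exact Poisson interval 18.4 to 27.8) and 10.9 in the E4 library (28 UMIs, 7.26 to 15.8), against 18.5 to 53.4 and 23.5 to 45.4 CPM in the 4 libraries of the same allele and age. Astrocytes held 1388 and 761 CPM, against 39.3 to 190 and 86.1 to 247 CPM, and near-empty droplets 35.4 and 46.8 CPM. The ratio of astrocytes to neurons was 61.1 and 69.6, against a median of 3.64 in the 32 libraries. With astrocyte levels this far apart, no loss or gain is read from the neuronal levels of the feature in either library. In DG granule nuclei, H2-D1 was at 11.6 CPM (21 UMIs, 7.15 to 17.7) in the E3 Syn-Cre library, against 4.91 to 11.3 in the 4 libraries of its allele and age. It was at 15.8 CPM (20 UMIs, 9.64 to 24.4) in the E4 Syn-Cre library, against 8.20 to 11.1 CPM. In the same E4 nuclei the control genes Clu and Cst3 were also above their ranges, at 33.14 CPM (13.12 to 24.47) and 82.06 CPM (31.99 to 68.99). In the E3 nuclei both controls were within them, at 25.31 CPM (14.04 to 26.5) and 70.97 CPM (41 to 77.85). B2m was within its range in both, at 8.253 CPM in E3 (4.494 to 10.34) and 4.734 CPM in E4 (3.645 to 6.389). No class I change is therefore read from H2-D1 here.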

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

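The correlation of neuronal with near-empty Apoe was a test chosen after the result was seen, and the other tests here were set before. The measures looked at, in groups of 4 libraries, were the shares of classes, total UMIs, the share of neurons with an Apoe UMI and Xist. Of 112 such groups 11 had a library far from the other 3, where 5.6 are expected by chance alone.

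Among shares of named nuclei, CA2/CA3 neurons made up 5.38% in E3_10mo replicate 3 and 8.27 to 8.74% in the other 3 libraries of its group. They made up 6.52% in E4_5mo replicate 3, with 8.84 to 9.20% in the others. Astrocytes were at 9.93% in E4_10mo replicate 4 (others 1.46 to 2.48%) and at 11.5% in E3_15mo replicate 4 (others 1.38 to 1.66%). OPC were at 1.39% in E3_10mo replicate 1 (others 2.22 to 2.35%) and microglia at 5.25% in E4_10mo replicate 1 (others 1.57 to 2.00%). Choroid plexus nuclei, a sign of how the tissue was dissected, made up 0.560% in E3_10mo replicate 3 (others 0 to 0.0466%) and 2.60% in E3_15mo replicate 4 (others 0.217 to 0.445%). E3_15mo replicate 4 also had 27.1 M UMIs, where the other 3 had 19.4 to 20.6 M. Xist, the RNA of the silenced X chromosome, stood at 2669 CPM in E3_10mo replicate 1, above 1647 to 1742 in the others. This library and E4_10mo replicate 1 are the letter H libraries of their groups, and Xist was at 2669 to 3005 CPM in the 4 of letter H and at most 2484 CPM in letters A, B and C.

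After thinning, 6.68% of neurons had an Apoe UMI in E4_10mo replicate 1, far from the 2.19 to 2.60% of the other 3 libraries, and the 4 of letter H had 4.23 to 6.68%. The astrocytes of the Syn-Cre libraries, which no comparison uses, had Apoe far above the libraries of their allele and age, at 1388 CPM in E3 (39.3 to 190) and 761 CPM in E4 (86.1 to 247).

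The pattern weighed is that of Apoe UMIs in neurons. Across the 32 libraries, with the mean of each code letter removed, neuronal Apoe rose with Apoe in near-empty droplets (Spearman's rho 0.403, permutation p = 0.0243, Pearson's r 0.374, p = 0.0217), and r was 0.489 without the 2 libraries farthest from the median and 0.505 over letters A, B and C alone. Free RNA that varies between libraries may thus explain part of the spread in neuronal Apoe. Whether it is the whole source cannot be told apart from expression in neurons, because the ratio of neuronal to near-empty CPM was 0.233, below the 90th percentile of 22 oligodendrocyte and microglial genes (0.463) and yet above 18 of these 22, so the rule written beforehand would pass a gene that most free RNA does not resemble. Glial RNA in the same droplet was not decided either, because 0 of 5 list tests of astrocyte and oligodendrocyte RNA showed a rise in neurons with an Apoe UMI and the control splits went both ways, with more calls than Apoe by Clu in each class and fewer by Cst3 in DG, CA1 and CA2/CA3 nuclei (0, 5 and 1 with edgeR, the 0 with 347 at an unadjusted p under 0.05). With no filter on low counts the astrocyte list did rise in DG nuclei (mean log2 0.19, fry p = 0.0065, n = 32 libraries). Expression in neurons, the biological explanation, stays open, and the human alleles have no feature of their own.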

How the results depend on the processing

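Depth sets the first limit: at 1466 to 3383 UMIs per nucleus, class I genes in neurons and most genes in astrocytes, OPC and microglia lie near or under the filter on low counts, so small changes there may go uncalled. In simulated data 51.7% of genes with a log2 change of 0.5 between genotypes were called in microglia and 62.0% in astrocytes. The Cell Ranger minimum, the removal of the letter H libraries and the sums of library pairs were chosen after seeing the data, and the other alternatives were planned. Here a count is called moved when it changes by more than 1.5 times. Without TMM factors 25 of 25 results of the comparisons kept their side of the threshold or stayed within 1.5 times, as did 25 of 25 at a mitochondrial maximum of 1%, and the 1 result each for no thinning and thinning to 500 UMIs. Among named genes and lists, 212 of 218 and 209 of 218 stayed the same in the first 2. Where no cause is given below, the cause was not tested.

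With DESeq2, 21 of 25 results stayed the same. The counts moved were age in CA1 (17), interneurons (1) and OPC (11) and genotype in microglia (1), and 193 of 203 named genes and lists kept their call. With no filter on low counts, which tests more genes, 10 of 29 stayed the same and 19 rose. Genotype counts were 452 in DG (257 shared with the 273), 534 in CA1, 248 in CA2/CA3, 16 in astrocytes, 27 in OPC and 14 in microglia. Age counts were 314 in DG, 162 in CA1, 19 in CA2/CA3, 10 in interneurons, 32 in OPC and 8 in microglia. The counts at 5, 10, 15 and 20 months were 324, 812, 339 and 239, the interaction gave 10, and the Apoe split gave 8 in DG and 13 in interneurons. In astrocytes the age count was 9, of which 1 was among the 6 genes called with the filter. Of named genes and lists 202 of 218 kept their side, 15 lost their call and 1 gained one.

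With no code letter, 9 of 25 stayed the same and 16 fell. Genotype counts were 124 in DG, 142 in CA1, 88 in CA2/CA3, 128 in interneurons, 55 in oligodendrocytes and 1 in microglia, and all 124 in DG were among the 273. Age counts were 43 in DG, 4 in CA1, 0 in CA2/CA3 with edgeR, 1 in interneurons, 0 in astrocytes and 73 in oligodendrocytes, and the single ages gave 106, 143, 109 and 103. Of named genes and lists 164 of 218 kept their call and 54 lost it. With the library pair as a block, 12 of 17 stayed the same and genotype counts rose to 429 in DG, 479 in CA1 and 225 in CA2/CA3, with 598 at 10 months and 1 for the interaction, and 127 of 127 named genes and lists kept their side. This block leaves age out, since the libraries of a pair have 1 age. With library pairs summed, 2 of 8 age counts stayed the same and 6 fell, to 55 in DG (53 shared with the 129), 3 in CA1, 0 in CA2/CA3 with edgeR, 1 in interneurons, 3 in astrocytes and 96 in oligodendrocytes, and 68 of 91 named genes and lists kept their side.

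At a minimum of 1000 UMIs, 45 of 53 stayed the same. This leaves few glial nuclei: genotype gave 4 in astrocytes and 16 in oligodendrocytes, and age 1 in astrocytes, 52 in oligodendrocytes and 8 in OPC. The Apoe split gave 3 in DG and 8 in CA1, the astrocyte share changed by -1.42 points with age and passed the threshold (adjusted permutation p = 0.0052), and 152 of 173 named genes and lists kept their side. With doublets removed at 2 times the rate, 54 of 56 stayed the same, the Apoe split gave 4 in DG and 15 in CA2/CA3, and 207 of 215 named genes and lists kept their side. With the Cell Ranger minimum, 49 of 53 stayed the same. Astrocytes had 1 gene with age, oligodendrocytes 23 between genotypes, the Apoe split gave 6 in DG, and the Cajal-Retzius share changed by -0.251 points with age (adjusted permutation p = 0.0507). Of named genes and lists 172 of 184 kept their side, 11 lost it, and 1 reversed, Fkbp5 with age in oligodendrocytes (log2 -0.018, adjusted p = 0.997, from 0.71). Without the letter H libraries, which leaves fewer samples, 45 of 52 stayed the same. The counts were 200 for genotype in CA1, 1 in microglia, 0 for age in CA2/CA3 with edgeR, 106 at 15 months, and 5, 10 and 2 for the Apoe split in CA1, CA2/CA3 and interneurons, and 192 of 216 named genes and lists kept their call. Without matching on depth, the Apoe split gave 123, 115, 39 and 88 in the 4 neuronal classes, which then differ in depth. As a share of glia, astrocytes changed by -5.60 points with age (adjusted permutation p = 0.0233), and the other 19 of 20 shares stayed the same.

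Leaving out each library in turn gave 1658 values for the comparisons, of which 1531 stayed the same, 71 fell and 56 rose. Age counts ranged from 68 to 146 in DG, 4 to 19 in CA1, 0 to 1 in CA2/CA3, 1 to 3 in interneurons, 2 to 10 in astrocytes, 101 to 168 in oligodendrocytes, 6 to 22 in OPC and 0 to 2 in microglia. Genotype counts ranged from 8 to 16 in OPC and 1 to 5 in microglia, and stayed within 222 to 284 in DG, 246 to 328 in CA1, 126 to 161 in CA2/CA3, 220 to 279 in interneurons, 5 to 7 in astrocytes and 83 to 116 in oligodendrocytes. The Apoe split ranged from 1 to 5 in DG, 6 to 20 in CA1, 5 to 37 in CA2/CA3 and 1 to 8 in interneurons, the interaction from 0 to 4, and the age change of the astrocyte share from -1.74 to -1.14 points. Of 158 called named genes, 115 kept their call without any 1 library and 43 lost it without at least 1. Microglia could not be fitted at 1000 UMIs or with the Cell Ranger minimum, no split at 2 or more Apoe UMIs could be made, and class I in astrocytes has a value only with no filter (E4 against E3 0.09, adjusted p = 0.923).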

Other observations

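The windows along the genome, the code letters for H2-D1, the Xist tests and the splits of whole library pairs were chosen after the results were seen, and the other tests here were set before.

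Some calls by the naming rule are not yet described. Between E4 and E3, Ddx58, which encodes the RNA sensor RIG-I, fell in DG granule nuclei (log2 -0.81, adjusted p = 0.0022), as did Pfkp, a phosphofructokinase (log2 -0.23). In CA2/CA3 nuclei the kinase gene Prkcd (log2 -0.60), the kainate receptor gene Grik4 (log2 -0.21) and the calcium channel gene Cacna1a (log2 -0.17) fell, and in CA1 Sparcl1 rose by 0.35 while Hs3st4 (log2 -0.35) and Rbfox3 (log2 -0.21) fell. The transcript Gm44151 fell in interneurons (log2 -1.03), astrocytes (log2 -0.87) and OPC (log2 -0.78). In oligodendrocytes Gria4 fell (log2 -0.22). Single libraries could each end the calls of Cacna1a (20, highest adjusted p = 0.118), Rbfox3 (12, 0.0759) and Gria4 (5, 0.0677). With age, DG granule nuclei had more Col6a1 (log2 1.55), Pfkfb3 (0.74), Snhg11 (0.31) and Rims2 (0.26) and less Lamp1 (log2 -0.41) and Cdh10 (log2 -0.65). Of these only Snhg11 kept its call without any 1 library. The calls of Col6a1, Pfkfb3, Rims2, Lamp1 and Cdh10 ended without any of 4, 8, 5, 8 and 11 libraries (highest adjusted p = 0.111, 0.123, 0.0997, 0.187 and 0.178). In oligodendrocytes Fkbp5, a gene induced by glucocorticoids, was at 0.71 (adjusted p = 0.030), a call that ended without any of 7 libraries (highest adjusted p = 0.207) and fell to log2 -0.018 with the Cell Ranger minimum. OPC had more Zfp804b (1.38), Rhoj (0.89) and Cntn3 (0.82), calls that ended without any of 3, 11 and 3 libraries (highest adjusted p = 0.390, 0.179 and 0.233).

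In oligodendrocytes the E4 excess of Serpina3n was 3.20, 2.26, 0.83 and 0.47 on the log2 scale at 5, 10, 15 and 20 months (adjusted p = 0.0010, 0.027, 0.85 and 1), while the age difference between genotypes was not past the threshold (adjusted p = 1). The value at 15 months was 1.38 without E3_15mo replicate 1. That at 20 months was 0.98 without E3_20mo replicate 2 and 0.26 without E3_20mo replicate 1 or without E3_20mo replicate 4. At 10 months the call ended without any 1 of E3_10mo replicates 1, 2 and 3 and E4_10mo replicates 1, 2 and 4 (adjusted p = 0.0555 to 0.259). In the Syn-Cre libraries, H2-K1 in DG granule nuclei was at 5.50 CPM in E3 (10 UMIs, 95% exact Poisson interval 2.64 to 10.1), with 1.12 to 2.26 in the 4 libraries of its allele and age. In E4 it was at 6.31 CPM (8 UMIs, 2.72 to 12.4), with 1.56 to 3.61 in the 4. The controls Clu and Cst3 were above their ranges in the E4 DG granule nuclei too, though not in E3, and B2m was within its range in both. No class I change is read from H2-K1 either. Oligodendrocyte H2-D1 was at 18.6 CPM in E3 (10 UMIs, 8.90 to 34.2, others 24.3 to 52.9) and 76.5 in E4 (26 UMIs, 49.98 to 112, others 16.5 to 51.4).

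Many genes differed between E4 and E3 in 1 direction in several classes. Of 179 such genes 12.3% lay within 20 Mb of Apoe, where 2.55% of tested genes lie, which is above the background and far below the share that a segment carried along with the targeted locus would need to be the main source. Depth is argued against as a source, since totals did not differ by genotype (permutation p = 0.802). Segments elsewhere that differ between the lines are a candidate explanation for part of the pattern: in a window of 10 Mb on chromosome 8, 28.6% of 28 tested genes were called in several classes, where the highest window over 10000 random sets had 19.0%. A test of close neighbours, set before, gave 375 called genes with another within 1 Mb, below the 5th percentile of random sets (382, median 405, 95th percentile 428). Age genes, which such segments do not explain, also fell below theirs (52, 5th percentile 74). By the limit set before, this test gave no sign of such segments. Random sets lay above called genes of either kind, so it cannot argue against them either. The window test, chosen after the results were seen, used random sets of the same kind. Whether any change is due to the allele or to such segments was not tested, and an effect of the human allele stays open.

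Of 5 class I genes measured in oligodendrocytes, H2-D1 and H2-K1 were called higher at 20 months and B2m was not (adjusted p = 0.10). The list of 5 lost its call with an estimated correlation (adjusted p = 0.16) and with library pairs summed (0.208). Microglial RNA in these droplets is argued against, because the microglia RNA list had a mean log2 change of -0.12 (SE 0.066, 4 genes) where class I had 0.74. A difference between code letters is argued against for H2-D1, which was higher at 20 months in 3 of 3 letters with both ages. A change of H2-D1 in oligodendrocytes with age is thus a hypothesis that may hold, found and tested on the same libraries. The call of H2-D1 held with library pairs summed (adjusted p = 1.45e-05), while those of H2-K1 and of the list did not. Without single libraries H2-K1 ranged from 1.11 to 1.74 on the log2 scale (1.29 with all) and the list from 0.66 to 0.94 (0.74), so the calls ended with folds of similar size.

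In 1 library of the E3 group at 15 months, replicate 4, Xist stood at 350.6 CPM against 1649 to 2099 in the 7 other libraries of its letter. Of its nuclei with at least 3000 UMIs, 23.6% had an Xist UMI against 97.7 to 99.1%. A candidate explanation is that most nuclei of this mouse carry 1 X chromosome. Over all nuclei, genes that escape silencing (Kdm6a, Kdm5c, Ddx3x and Eif2s3x) summed to 217 CPM against 247.7 to 295.9. Among its nuclei of at least 3000 UMIs they summed to 188.9 CPM without and 229.4 CPM with an Xist UMI. The sum was lower without one in each of the 4 neuronal classes, but with overlapping intervals (in CA1 196.1 and 205.2 CPM). Since 229.4 is also below 247.7, 1 X chromosome may not account for the whole gap. Genes of the Y chromosome were at 2.45 CPM, within the 1.07 to 7.55 of the 33 other libraries. Without this library the genotype counts were 234 in DG, 321 in CA1, 150 in CA2/CA3, 253 in interneurons and 100 in oligodendrocytes, and the age counts 120 in DG and 153 in oligodendrocytes.

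Other splits of the same libraries were run for each count. For E4 against E3, with genotype permuted within age, the real split was the only 1 of 60 to reach its count in every class. This is a share under 0.05 in each class, with no correction over the 8 classes. The real counts and the highest of the other splits were 273 and 6 in DG, 304 and 3 in CA1, 149 and 10 in CA2/CA3, 271 and 6 in interneurons, 7 and 1 in astrocytes, 108 and 8 in oligodendrocytes, 9 and 5 in OPC and 2 and 1 in microglia. Because libraries come in pairs, 40 splits that part every pair as the real one does were run too, the real one included. The highest counts of the others were larger or, in microglia, equal, at 79, 82, 42, 102, 3, 33, 6 and 1 in the same order, each below the real count. In astrocytes, OPC and microglia the margins were of few genes (7 against 3, 9 against 6 and 2 against 1), so chance is not excluded there.

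At single ages only the real split reached its count at 5 months (1 of 30 splits, 183 against 6), 10 months (1 of 29, 264 against 28) and 15 months (1 of 28, 174 against 27). These are shares under 0.05 with no correction over the 4 ages. At 20 months chance cannot be excluded, since 2 of 27 splits reached the real count of 157. The other of these called 178 genes and keeps all 4 library pairs together, which points to a structure of the samples by pair. With the pair as a block 203 genes were called at 20 months, and splits that part all 4 pairs as the real one does called at most 1. For the difference in age change between genotypes, 0 genes were called, so all 60 splits reached the count (up to 28) and they say nothing about it.

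For age, libraries of a pair fall at the same age, so splits of the 8 whole pairs of 5 and 20 months are the test. There are 35 with the real one. Only the real split reached its count in astrocytes (1 of 35, 6 against 2 in the highest other), oligodendrocytes (1, 153 against 48) and OPC (1, 18 against 12). This is a share under 0.05 in each, with no correction over the 8 classes. Chance cannot be excluded in DG (3, 129 against 843), CA1 (4, 11 against 800), CA2/CA3 (8, 1 against 418) or interneurons (5, 2 against 225). Splits that call several times the real count point to a structure of the samples, and those highest counts come from splits that put all pairs of at least 1 code letter on 1 side, though the letter is a covariate in these fits. Among the 17 others with all 3 letters on both sides, as in the real split, the highest were 8, 7, 2 and 1 in these 4 classes. In astrocytes, oligodendrocytes and OPC they were 0, 21 and 3. Yet 18 splits are too few for a share under 0.05 in any class. With the pairs summed the counts were 55 in DG, 3 in CA1, 1 in interneurons and 0 in CA2/CA3 with edgeR.

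Splits of single libraries within genotype, planned first, break the pairs and are not used for age. Of 60, those that reached the real count were 1 in DG (highest other 0), 1 in CA1 (9), 3 in CA2/CA3 (1), 2 in interneurons (8), 1 in astrocytes (1), 1 in oligodendrocytes (22) and 1 in OPC (3). In microglia 0 genes were called, so all 60 splits (up to 3) and all 35 of whole pairs (up to 1) reached the count and say nothing. For the Apoe split, sides were swapped in random sets of libraries. Only the real split reached its count in CA1 (1 of 41, 13 against 2), CA2/CA3 (1, 23 against 8) and interneurons (1, 6 against 5), while in DG 5 did (1 against 1). In interneurons 6 against 5 is too close to exclude chance. Swaps test only whether the 2 sides differ at all, and 9, 7 and 4 of 20 random genes gave as many calls in CA1, CA2/CA3 and interneurons. They thus show nothing particular to Apoe.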
